A study of Homo sapiens with 29 samples.

How the data were processed

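Polyadenylated RNA was measured in 29 libraries of WM239A melanoma cells in 10 groups: vector and BRAF-V600E cells without drug, BRAF-V600E cells after 20 hours and 7 days of LGX818 at 500 nM, and the continuous and intermittent arms at weeks 2, 3 and 4. Per the labels, cells were trypsinized and frozen and the RNA of all samples was purified at the end of the time course. Groups held 3 libraries, except week 4 under continuous drug, which held 2.

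The deposited table holds raw read counts per gene, in whole numbers, for 60675 Ensembl genes. Per the labels the processing used Trimmomatic 0.32, HISAT2 2.0.3, SAMtools 0.1.18 and HTSeq 0.6.1 with the GRCh38 genome. The annotation release and the strand setting of the counting are not given, so counts of genes that overlap another gene on the opposite strand are uncertain. Gene symbols were taken from the deposited table, and 13 symbols belong to more than 1 tested gene. Positions and types were taken from GENCODE 29, which matched 57055 of the identifiers and 20326 of the tested genes. The intermittent week 3 columns are named as off drug in the table but as on drug in the sample labels. They were assigned by week, schedule and replicate number, which match no other sample.

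Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr, 1 quasi-likelihood fit of all 29 libraries with a term for each group, and Benjamini-Hochberg adjustment within each comparison at a threshold of 0.05. This left 20494 genes, which held at least 99.95% of the counts of every library, with a common biological coefficient of variation of 0.0868. Standard errors of log2 changes were derived from the estimate and its F statistic. There were 17 comparisons, 9 main and 8 secondary. Rechallenge was tested as the change from week 2 off drug to week 3 on drug minus the change from untreated to week 1, and the second withdrawal against the first in the same way. Means and SD are in CPM.

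A set of 24 gene lists was tested with camera in limma 3.58.1 on log2 CPM (prior count 2, trended variance, inter-gene correlation preset to 0.01), adjusted over the lists of a comparison, for lists with at least 5 tested members. Where a call did not hold with the correlation estimated per list, that adjusted p is given too. Counts of members were also adjusted over the list alone. Library measures (total counts, mitochondrial share and share of the 10 largest genes) were compared by exact two-sided permutation tests. Overlaps of calls were taken for comparisons that share no libraries. Groups at 0 counts were given a floor of 3 counts over the group. Genes with 1 to 3 counts in a group are given as a ratio with a 95% counting interval.

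The comparisons, lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names 12 genes in every main comparison. It adds the 6 largest rises and 6 largest falls past the threshold with a mean of at least 5 CPM and libraries that do not overlap between the groups. Clone names, bare identifiers and pseudogenes are left out of it, and overlap was not asked of the interactions. With 3 libraries against 3, chance alone keeps groups apart for 10% of genes. Up to 2 members of each called list in its direction and 1 against it are named as well. Values of a few genes that the rule names are not reported here. BRAFP1, LYZ, PECAM1 and the fibroblast markers given in the closing section fall outside that rule.

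Alternatives were DESeq2 1.42.0, RLE factors, no count filter, the libraries of the compared groups alone, a term for the replicate number, leaving out each library in turn, and for lists the estimated correlation, fry and DESeq2 statistics. A further alternative, leaving out together the 4 libraries that stood apart from their group (replicate chi-square per gene over 20 against both others), was chosen after seeing the data. Where leaving out a library left week 4 under continuous drug with 1 library, that library was assumed to vary like the other groups.

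The procedure was tested on counts simulated for all 29 libraries from their mean expression, library sizes and dispersions. In these, 200 genes were changed at week 1, which was compared with untreated cells. The procedure recovered 26 of 67 genes changed 1.5-fold (38.8%), 42 of 67 changed 2-fold (62.7%) and 51 of 66 changed 4-fold (77.3%) among 19323 tested, with 6 false calls (4.8% of calls). The real comparison called far more genes, so these rates need not carry over to it. A raised list reached 2.70e-41 in the list test before adjustment. An unchanged list came out at 0.0363, and of 200 further unchanged lists 2 (1%) were under 0.05, none after adjustment, with 0.0176 as the smallest. Genes were simulated independently of each other, so these list results say nothing about lists whose members vary together. Libraries of 22.9 to 35.8 mega-counts were not scaled down to a common depth. Figures were drawn with matplotlib 3.10.9 in python 3.11.15. No column of the table was left out. The leukocyte and endothelial list, with 4 tested members, had no list test.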

Results

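Polyadenylated RNA was sequenced from WM239A cells, a human metastatic melanoma line, in 29 libraries that form 10 groups. Cells with an empty vector and cells overexpressing BRAF-V600E, the mutant kinase that drives the MAPK pathway in many melanomas, were sequenced without drug (3 libraries each). BRAF-V600E cells were also sequenced after 20 hours in 500 nM LGX818 (encorafenib), an inhibitor of the BRAF kinase, and after 7 days in it, called week 1 here (3 libraries each). From there a continuous arm stayed on drug and was sampled at 14, 21 and 28 days, here weeks 2, 3 and 4 (3, 3 and 2 libraries). An intermittent arm alternated 7 days on drug with 7 days off it. It was sampled off drug at week 2, back on drug at week 3 and off drug again at week 4 (3 libraries each). No untreated cells were sampled late in the course, so comparisons of later weeks with untreated cells include time in culture. The labels do not say whether the libraries of a group came from separate cultures, so every p-value measures the spread between these libraries.

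Total counts per library, in mega-counts (M), were 30.6, 27.1 and 23.3 M in vector cells, 24.7, 30.7 and 26.3 M in untreated BRAF-V600E cells, and 22.9, 23.4 and 25.2 M at 20 hours. They were 26.9, 35.8 and 31.4 M at week 1. The continuous arm had 24.0, 29.2 and 27.2 M at week 2, 25.0, 34.2 and 32.8 M at week 3, and 31.0 and 29.5 M at week 4. The intermittent arm had 26.1, 30.5 and 31.4 M at week 2, 32.1, 32.3 and 30.6 M at week 3, and 28.9, 32.6 and 30.1 M at week 4. Of 60675 genes listed, 39110 had any count and 20494 were tested. Mitochondrially encoded genes held 15.7% ± 0.714 (SD, n = 3) of the counts in untreated BRAF-V600E cells, 19.5% ± 1.62 at 20 hours and 10.3% ± 0.857 at week 1. Exact two-sided permutation tests gave p = 0.1 for both differences, the smallest that 3 libraries against 3 allow (adjusted p = 0.24 over 24 such tests).

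In the deposited table the intermittent week 3 columns are named as off drug, while the sample labels say on drug, and the labels were followed. DUSP6, a phosphatase induced by ERK activity, stood at 109 ± 7.75 CPM (SD, n = 3) in those libraries against 658 ± 17.97 off drug at week 2. On the first principal component (38.6% of the variance) the vector, untreated and 20-hour groups had means from -116.1 to -100, and all later groups from 25.4 to 65.6. On the second (26.7%) the off-drug groups lay at -122.5 and -101.4, and the other 8 groups between -22.2 and 54.2.

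**Figure D1:**
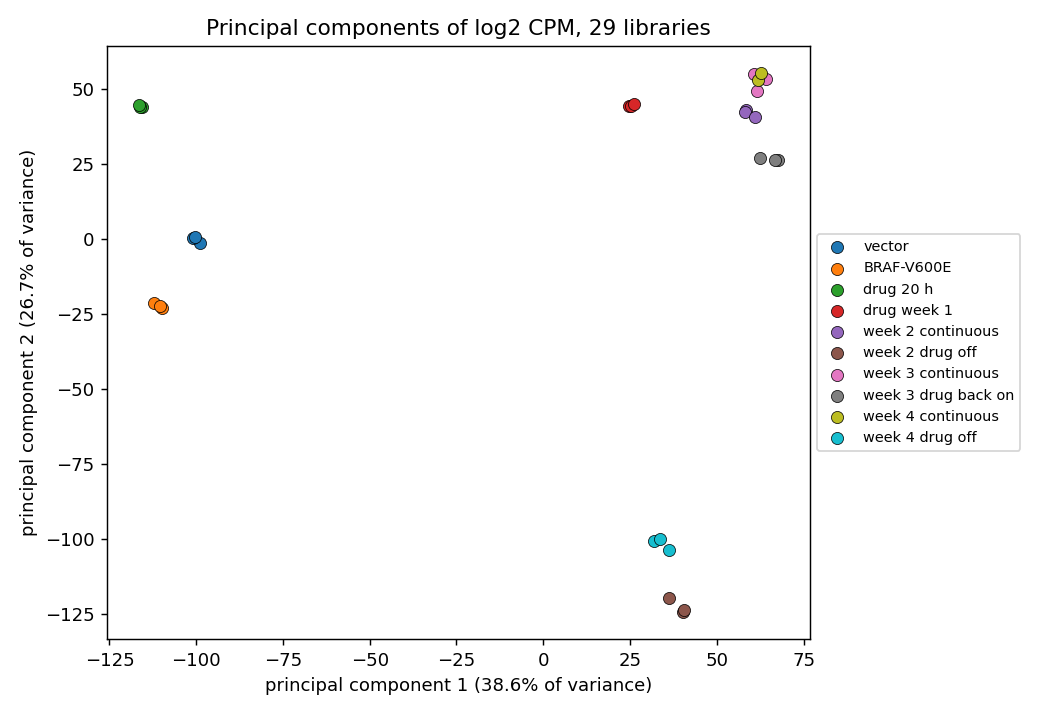
Principal components 1 and 2 of log2 CPM, with their shares of variance on the axes, 1 point per library and 1 colour per group. The off-drug libraries of weeks 2 and 4 sit at the bottom, with group means of -122.5 and -101.4 on component 2.

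A fixed set of 12 genes was followed in every comparison. On GRCh38 these are BRAF (ENSG00000157764, chromosome 7, 140719327 to 140924928), DUSP6 (chromosome 12, 89347232 to 89353271), SPRY4 (chromosome 5, 142310427 to 142326455) and ETV4 (chromosome 17, 43527844 to 43579620). CCND1 (chromosome 11, 69641087 to 69654474), FOSL1 (chromosome 11, 65892049 to 65900573), EGR1 (chromosome 5, 138465490 to 138469315) and MITF (chromosome 3, 69739435 to 69968337) follow. The last are TYR (chromosome 11, 89177452 to 89295759), AXL (chromosome 19, 41219203 to 41261766), MKI67 (chromosome 10, 128096659 to 128126385) and CDKN1A (chromosome 6, 36676460 to 36687339). BRAF shares sequence with the pseudogene BRAFP1 (ENSG00000224775, chromosome X, 75582676 to 75585506), which held 4.28 CPM in untreated BRAF-V600E cells.

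The first comparison asked what added BRAF-V600E changed without drug. BRAF stood at 895 ± 7.17 CPM (SD, n = 3) against 40.2 ± 2.83 in vector cells, 22.3-fold higher (log2 4.48 ± 0.09 SE, adjusted p = 1.26e-25). Fixed genes that are targets or feedback inhibitors of ERK went different ways. SPRY4 rose 1.57-fold, DUSP6 1.49-fold and the transcription factor ETV4 1.32-fold. FOSL1 fell by 0.97 on the log2 scale, and CCND1 did not pass (0.09, adjusted p = 0.375). The immediate early gene EGR1 rose by 1.38 on the log2 scale (SE 0.11, adjusted p = 5.73e-11). MHC class II genes, which present antigen to helper T cells, moved the other way. HLA-DRA was 9.9-fold lower (5.87 ± 0.488 against 58.3 ± 1.16 CPM), and CIITA, the master activator of that gene family, was 9.51-fold lower. SH2D1B, the natriuretic peptide receptor NPR1, phospholamban (PLN), LAD1 and the G-protein regulator RGS5 rose most after BRAF, with log2 changes from 3.16 to 5.01. MYOF, OLFML2A, VASN and HLA-DPA1 fell most beside the class II pair, with changes from -3.65 to -2.78. The receptor kinase AXL fell by 0.90, and the pigment enzyme TYR fell by 0.53. MITF (0.01, adjusted p = 0.987), the proliferation marker MKI67 (-0.05, 0.92) and the CDK inhibitor CDKN1A (-0.14, 0.218) did not pass.

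By gene group, 6 of 8 class II genes fell and 2 rose, with the same counts adjusted over the list alone (list test adjusted p = 5.75e-08). Of 14 neural crest genes 8 fell and 2 rose (9 and 2 adjusted over the list alone, adjusted p = 1.83e-06), with NGFR at -1.78 and L1CAM at -1.40 and RXRG rising by 1.08. The ERK output list rose in 10 of 23 genes and fell in 4, the same adjusted over the list alone (adjusted p = 0.00841, adjusted p = 0.14 with an estimated correlation). DUSP5 led it at 2.69, and EPHA2 fell by 1.00. Melanocyte genes fell in 11 of 19 and rose in 2, the same adjusted over the list alone (adjusted p = 1.98e-05, adjusted p = 0.0618 with an estimated correlation), with TRPM1 at -2.30, DCT at -1.99 and RAB27A rising by 0.36. Invasive-state genes fell in 9 of 20 and rose in 3 (11 and 3 adjusted over the list alone, adjusted p = 6.73e-04, adjusted p = 0.0618 with an estimated correlation), with LOXL2 at -1.28, CTGF at -1.11 and WNT5A rising by 1.94. Their median of -0.61 is -0.52 with PLAU, which had no count in 1 group, at its bound. ATF4 targets rose in 12 of 18 (14 adjusted over the list alone, with 3 lower, adjusted p = 5.75e-08, adjusted p = 0.0618 with an estimated correlation), with TRIB3 at 1.22 and asparagine synthetase (ASNS) at 0.84. Glycolysis genes rose in 9 of 21 and fell in 1, the same adjusted over the list alone (adjusted p = 9.25e-05, adjusted p = 0.14 with an estimated correlation), with LDHA at 0.49 and PDK1 at 0.47. The gene that fell, CA9, had 3 counts against 46, a ratio of 15.1 with a 95% counting interval of 4.86 to 76. Ribosome biogenesis rose in 5 of 18 (9 adjusted over the list alone, adjusted p = 0.00436, adjusted p = 0.14 with an estimated correlation), with DKC1 at 0.26 and NPM1 at 0.36. Lysosome genes fell in 12 of 20 and rose in 1 (15 and 2 adjusted over the list alone, adjusted p = 1.85e-07, adjusted p = 0.144 with an estimated correlation), with CTSA at -0.53 and CTSB rising by 0.30. MHC class I genes fell in 5 of 14, the same adjusted over the list alone (adjusted p = 0.0358, adjusted p = 0.503 with an estimated correlation), with HLA-E at -0.44 and NLRC5 at -0.69. That call was lost without vector replicate 1 (adjusted p = 0.0931) or BRAF-V600E replicate 1 (adjusted p = 0.0869), or with DESeq2 statistics (adjusted p = 0.0825). In all, 1442 genes were higher and 2034 lower at adjusted p under 0.05 (edgeR quasi-likelihood test), 340 and 496 of them at least 2-fold. Counting intervals and floors here cover counting error only.

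**Figure D2:**
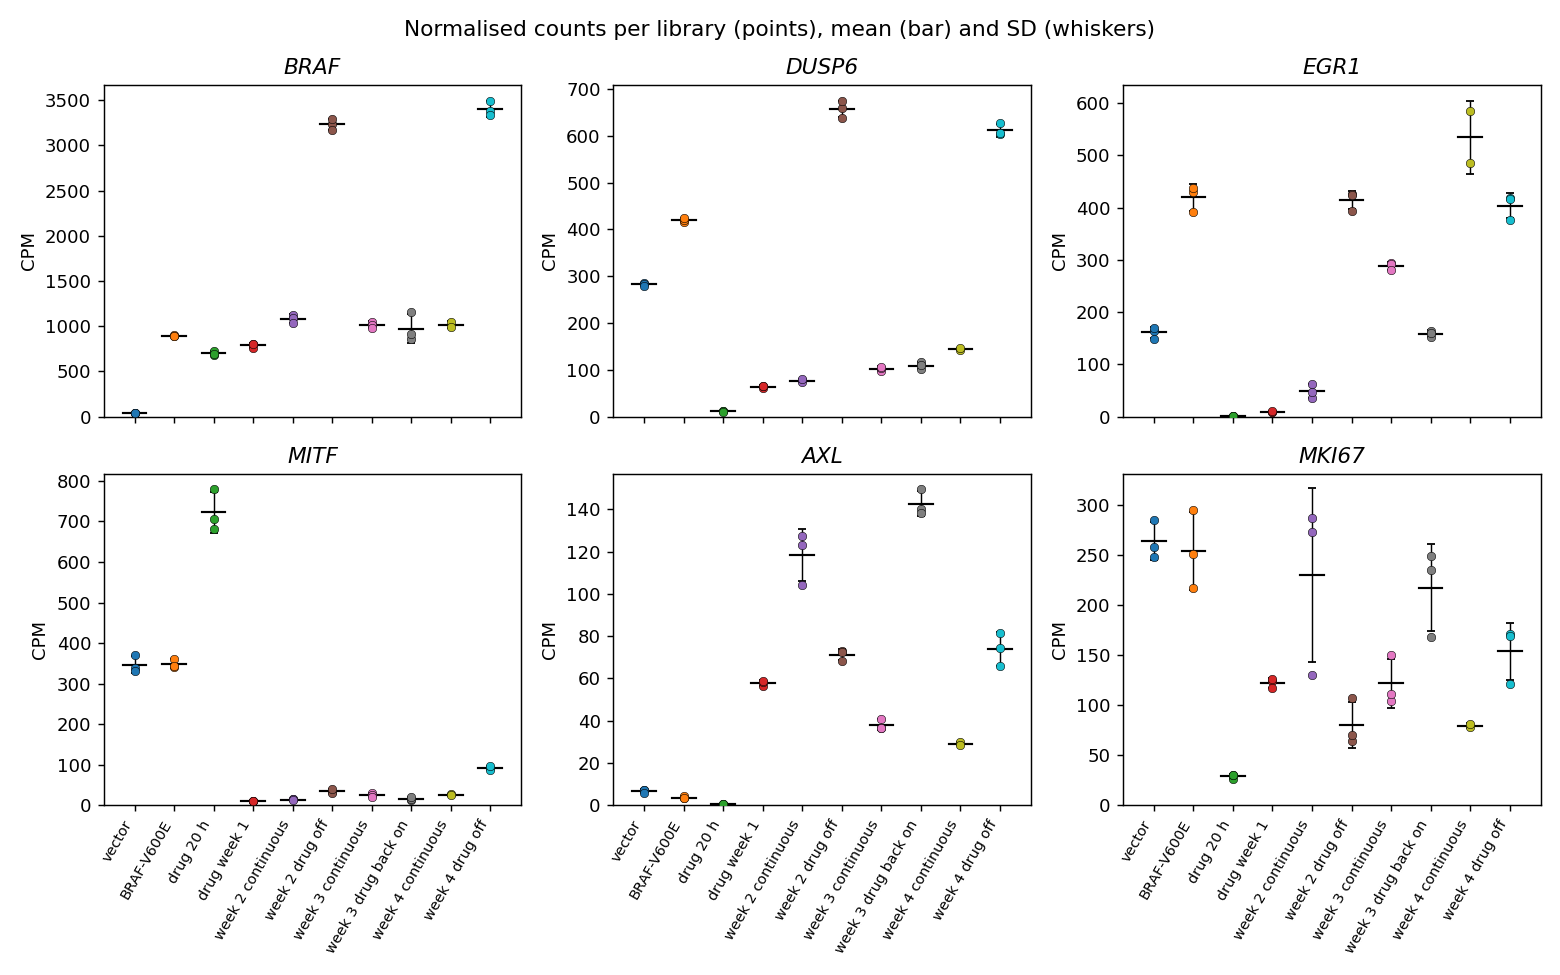
CPM of BRAF, DUSP6, EGR1, MITF, AXL and MKI67 in each library (points) with group mean (bar) and SD (whiskers), groups along the horizontal axis. BRAF is highest off drug at weeks 2 and 4, at means of 3232 and 3404 CPM, and DUSP6 is low in every group on drug.

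The second comparison asked what 20 hours of LGX818 did to BRAF-V600E cells. ERK targets collapsed: EGR1 was 278-fold lower (1.502 ± 0.256 against 420 ± 25.1 CPM, SD, n = 3), SPRY4 157-fold, ETV4 104-fold, DUSP6 38.2-fold, cyclin D1 (CCND1) 21.7-fold and FOSL1 11.1-fold lower. Pigment-cell genes rose, with MITF, the melanocyte master regulator, at 2.07-fold and TYR at 2.85-fold (978 ± 29.9 against 344 ± 8.74 CPM). MKI67 was 8.77-fold lower and AXL 5.94-fold lower, and BRAF itself fell by 0.35 on the log2 scale (SE 0.08, adjusted p = 2.38e-04). The largest rises were those of the potassium channel gene KCNJ13 (82.8 ± 2.47 against 0.104 ± 0.1 CPM), CDK15, the pigment enzyme TYRP1, MATN2, TNS1 and the melanocyte channel TRPM1, with log2 changes from 5.39 to 9.67. EGR3, SH2D1B and the lipase MGLL completed the largest falls at -7.61, -6.37 and -6.37. CDKN1A did not pass (0.07, adjusted p = 0.429).

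Of 23 ERK output genes 21 fell and 2 rose, the same adjusted over the list alone (adjusted p = 2.93e-22), and EMP1 was 1 of those that rose, by 0.90. All 20 G1/S genes and all 20 G2/M genes fell, the same adjusted over the list alone (adjusted p = 3.60e-24 and 5.96e-23), with the nucleotide reductase RRM2 at -5.04, CDC6 at -5.01, UBE2C at -4.27 and TPX2 at -2.90. All 18 ribosome biogenesis genes fell, also adjusted over the list alone (adjusted p = 7.75e-13), with DKC1 at -1.69 and NOLC1 at -1.47. Melanocyte genes rose in 14 of 19 and fell in 2, the same adjusted over the list alone (adjusted p = 5.50e-07), with PAX3 at 2.83 and MC1R at -0.94. Invasive-state genes fell in 12 of 20 and rose in 2 (13 and 2 adjusted over the list alone, adjusted p = 5.58e-07), with WNT5A at -3.49, CTGF at -2.23 and SLIT2 rising by 0.98. Secreted inflammatory factors fell in 11 of 17, the same adjusted over the list alone (adjusted p = 1.25e-06), with the cytokine LIF at -5.63 and the collagenase MMP1 at -2.84. Their median of -2.67 is -2.52 with IL6 and CSF2 at their bounds. Glycolysis and hypoxia genes fell in 17 of 21, the same adjusted over the list alone (adjusted p = 2.37e-10), with NDRG1 at -2.96 and PFKFB4 at -2.62. Immediate early genes fell in 11 of 15 and rose in 3, the same adjusted over the list alone (adjusted p = 3.21e-05, adjusted p = 0.0622 with an estimated correlation), with JUN rising by 2.68. Lysosome genes rose in 16 of 20 and fell in 3 (16 and 4 adjusted over the list alone, adjusted p = 7.42e-06, adjusted p = 0.237 with an estimated correlation), with CTSA at 1.51, HEXA at 1.27 and NPC1 at -1.05. Cholesterol synthesis genes fell in 13 of 19 and rose in 2 (14 and 3 adjusted over the list alone, adjusted p = 0.00223, adjusted p = 0.102 with an estimated correlation), with LSS rising by 0.54. The test counted 5830 genes higher and 5173 lower, 2388 and 2219 at least 2-fold.

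The third comparison asked how cells looked after 7 days of drug against untreated BRAF-V600E cells. The pigment program, up at 20 hours, was now down: MITF was 30.6-fold lower (11.4 ± 0.234 against 349 ± 10.7 CPM, SD, n = 3) and TYR fell by 1.41 on the log2 scale. AXL was 15.9-fold higher (57.9 ± 1.37 against 3.61 ± 0.59 CPM), with thrombospondin THBS1 at 8073 against 87.1 CPM and NGFR at 360 against 7.61 CPM. ETV4, SPRY4 and DUSP6 stayed 20.4-, 12.2- and 6.58-fold lower and EGR1 45.5-fold lower. CCND1 fell by just 0.47, and FOSL1 rose by 1.84. MKI67 fell by 1.06 (SE 0.21, adjusted p = 6.08e-05) and CDKN1A was 2.35-fold higher. The small heat shock gene CRYAB, MYOF, OLFML2A and the cadherin CDH6 rose by 8.84 to 10.33. HSPB3 had no count in untreated cells and was at least 338-fold higher, and the apelin receptor APLNR had 1081 counts against 2, a ratio of 489 (95% counting interval 135 to 4040). The connexin GJB1 was 539-fold lower and the antisense transcript LHFPL3-AS1 fell by 9.10, read with caution because the strand setting of the counting is not stated. SLC5A4, MUC7 and NHEG1 each kept 1 count, at ratios of 5419 (972 to 214100), 1610 (288 to 63620) and 1004 (180 to 39720), and LAD1 kept 3 (593, 202 to 2878). BRAF fell by 0.18 (SE 0.08, adjusted p = 0.0434). That call did not hold with DESeq2 (0.0506), RLE factors (0.0557) or no count filter (0.134), nor without BRAF-V600E replicate 1 (0.127), 2 (0.0902) or 3 (0.1), or week 1 replicate 2 (0.144) or 3 (0.0809). Over all alternatives this adjusted p for BRAF ran from 0.00496 to 0.144.

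Invasive-state genes rose in 16 of 20 and fell in 3, the same adjusted over the list alone (adjusted p = 1.26e-07), with SOX9 at -1.47. The median of 2.79 is 2.66 with PLAU at its bound. Neural crest genes rose in 10 of 14 and fell in 2, the same adjusted over the list alone (adjusted p = 8.39e-06), with L1CAM at 4.40 and RXRG at -4.81, and a median of 1.91, or 1.59 with TFAP2B at its bound. Melanocyte genes fell in 13 of 19 and rose in 3, the same adjusted over the list alone (adjusted p = 3.26e-06), with SLC45A2 at -3.23 and TYRP1 still up by 5.82. ERK output fell in 18 of 23 and rose in 5, the same adjusted over the list alone (adjusted p = 3.60e-07), with DUSP4 at -3.11 and EMP1 rising by 2.61. All 8 class II genes fell, also adjusted over the list alone (adjusted p = 1.09e-05), with HLA-DMB at -5.89 and CD74 at -2.90. Cholesterol synthesis fell in 17 of 19 and rose in 1, the same adjusted over the list alone (adjusted p = 2.37e-08), with STARD4 at -2.69. ATF4 targets rose in 16 of 18 and fell in 1 (17 and 1 adjusted over the list alone, adjusted p = 6.08e-09), with ATF3 at 4.04, SESN2 at 2.57 and VLDLR at -0.52. Other groups were called by camera with the preset correlation but not with an estimated one. G1/S genes fell in 17 of 20 (18 adjusted over the list alone, adjusted p = 7.54e-07, adjusted p = 0.0616 with an estimated correlation), with MCM6 at -1.25 and MCM3 at -1.07. G2/M genes fell in 19 of 20, the same adjusted over the list alone (adjusted p = 8.96e-07, adjusted p = 0.0953 with an estimated correlation), with NUSAP1 at -0.85 and CCNA2 at -0.86. Oxidative phosphorylation genes fell in 21 of 24, the same adjusted over the list alone (adjusted p = 8.41e-06, adjusted p = 0.151 with an estimated correlation), with PPARGC1A, a driver of mitochondrial biogenesis, at -5.18 and ATP5C1 at -1.06. The share of mitochondrially encoded counts was 10.3% against 15.7%. Glycolysis fell in 16 of 21 and rose in 3, the same adjusted over the list alone (adjusted p = 9.09e-05, adjusted p = 0.0953 with an estimated correlation), with VEGFA rising by 2.04.

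Secreted factors rose in 10 of 17 and fell in 3, the same adjusted over the list alone (adjusted p = 0.00549, adjusted p = 0.123 with an estimated correlation), with IL11 at 4.37, HBEGF at 2.14 and LIF at -1.92. Lysosome genes rose in 12 of 20 and fell in 6, the same adjusted over the list alone (adjusted p = 0.0124, adjusted p = 0.454 with an estimated correlation), with WIPI1 at 1.53 and GLB1 at 1.13. Ribosome biogenesis fell in 12 of 18 and rose in 2, the same adjusted over the list alone (adjusted p = 0.00634, adjusted p = 0.123 with an estimated correlation), with POLR1B at -1.36, NCL at -0.58 and RRP9 rising by 0.65, a call lost with DESeq2 statistics (adjusted p = 0.0561). Class I genes rose in 7 of 14, the same adjusted over the list alone (adjusted p = 0.0436, adjusted p = 0.418 with an estimated correlation), with PSMB9 at 2.46 and TAPBP at 0.59, and lost the call without BRAF-V600E replicate 1 (adjusted p = 0.0649) or week 1 replicate 2 (adjusted p = 0.0626) or with DESeq2 statistics (adjusted p = 0.097). Fibroblast markers rose in 5 of 10 and fell in 2, the same adjusted over the list alone, with COL1A1 at 224 against 0.778 CPM, COL1A2 at 17.7 against 0.183 and COL3A1 at 10.3 against 0.0595. That list did not pass (adjusted p = 0.0581, adjusted p = 0.0953 with an estimated correlation) except with DESeq2 statistics (adjusted p = 0.0157), no count filter (0.00913) or fry (4.68e-15), or without BRAF-V600E replicate 2 (0.0481) or 3 (0.0427) or week 1 replicate 1 (0.0455). At week 1, 5635 genes were higher and 5463 lower than in untreated cells, 2630 and 2310 at least 2-fold.

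The fourth comparison asked what a week off drug did, against a second week on it. BRAF was 2.99-fold higher off drug (3232 ± 59.9 against 1082 ± 48.5 CPM, SD, n = 3; log2 1.58 ± 0.08 SE, adjusted p = 4.97e-17). Most ERK targets among the fixed genes came back with it: SPRY4 and ETV4 were both 10.9-fold higher, EGR1 8.56-fold and DUSP6 8.53-fold higher. CCND1 rose by 0.97 on the log2 scale, while FOSL1 changed by -0.50. Secreted factors surged, with the growth factor amphiregulin (AREG) at 100.5 ± 14.4 against 0.306 ± 0.131 CPM and LIF at 861 against 53.5 CPM. MKI67 fell by 1.52 (SE 0.21, adjusted p = 3.13e-07) while CDKN1A rose by 0.81. Collagen COL1A1 was 237-fold lower (4.44 ± 1.45 against 1054 ± 23.6 CPM). MITF rose by 1.34 and TYR by 0.59, and AXL changed by -0.73. Tear lipocalin LCN1 and mast-cell tryptase TPSAB1 had no count on drug and were at least 628-fold and 402-fold higher. LCE1F, the interleukin-36 antagonist IL36RN and CD52 had 1, 2 and 3 counts on drug, at ratios of 3986 (715 to 157500), 1870 (517 to 15450) and 1733 (593 to 8405), and IL36B was 1447-fold higher. The BMP antagonist GREM1 had no count off drug and was at least 286-fold lower, and NPPB, the fatty acid receptor CD36 and LYPD6B changed by -9.02, -8.09 and -7.88.

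Of 23 ERK output genes 20 rose and 3 fell, the same adjusted over the list alone (adjusted p = 3.09e-12), with DUSP5 at 4.44 and EPHA2 at -0.99. All 20 G2/M genes and 19 of 20 G1/S genes fell, the same adjusted over the list alone (adjusted p = 2.71e-15 and 1.13e-09), with KIF20A at -2.26, TPX2 at -1.77, TYMS at -1.34 and RRM2 at -1.02. Week 2 continuous replicate 3 stood apart from its group here: its chi-square per gene against the other replicates was 54.2 and 72.5, against 8.89 between those, and it held 130 CPM of MKI67 where they held 287 and 272. Its G2/M list as a whole was not lower to that degree, at a mean log2 CPM of 6.46 against 6.58 and 6.51. Week 2 off-drug replicate 3 stood apart less, at 25.3 and 26.9. Secreted factors rose in 13 of 17 and fell in 3, the same adjusted over the list alone (adjusted p = 9.69e-06), with IL6 at -5.19. Melanocyte genes rose in 11 of 19 and fell in 3, the same adjusted over the list alone (adjusted p = 0.0381, adjusted p = 0.37 with an estimated correlation), with PMEL at 3.81, RAB27A at 0.98 and TYRP1 at -1.79. Class II genes rose in 6 of 8 and fell in 1, the same adjusted over the list alone (adjusted p = 0.0338, adjusted p = 0.37 with an estimated correlation), with HLA-DMB at 3.96, CD74 at 1.79 and CTSS at -0.90, a call lost with DESeq2 statistics (adjusted p = 0.0709). Lysosome genes rose in 15 of 20 and fell in 3, the same adjusted over the list alone (adjusted p = 1.09e-04, adjusted p = 0.37 with an estimated correlation), with cathepsin B (CTSB) at 1.94, NPC1 at 1.68 and CTSD at -0.96. Fibroblast markers fell in 6 of 10 and rose in 3, the same adjusted over the list alone (adjusted p = 0.0381, adjusted p = 0.0834 with an estimated correlation), with FAP at -1.46 and COL6A3 rising by 3.54. The leukocyte and endothelial list had 4 tested genes, too few for a list test, and all 4 rose, lysozyme (LYZ) from 0.262 to 4.72 CPM and PECAM1 from 0.12 to 2.78 CPM. Epithelial markers had a mean log2 CPM of 2.3 to 2.36 per library off drug and 1.22 to 1.57 on drug. Off drug, 5598 genes were higher and 5720 lower than on continuous drug, 2825 and 2205 at least 2-fold.

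The fifth comparison asked whether cells back on drug at week 3 differed from cells that never left it. DUSP6 stood at 109 ± 7.75 against 103 ± 4.57 CPM (SD, n = 3; log2 0.08, adjusted p = 0.368) and BRAF at -0.06 (adjusted p = 0.636, or -0.18 and 0.0376 without the rechallenged replicate 3). CDKN1A did not pass either (0.11, 0.263), and SPRY4 rose by 0.32. Cell cycle genes were higher in the rechallenged cells, with CCND1 at 2.54-fold (1074 ± 40.8 against 423 ± 2.58 CPM) and MKI67 at 1.78-fold (log2 0.84 ± 0.21 SE, adjusted p = 0.00222). The continuous arm itself had changed since week 2. Its mean log2 CPM of the G2/M list went from 6.46 to 6.58 per library down to 5.73 to 5.8. Rechallenged cells held 6.47 to 6.58. Its interferon-response list went from 2.62 to 2.78 up to 3.46 to 3.61, against 2.48 to 2.56 in rechallenged cells. Total time on drug differs between the arms and cannot be told apart from history. In rechallenged cells AXL was 3.76-fold higher (143 ± 5.98 against 38.0 ± 2.56 CPM), ETV4 2.1-fold and FOSL1 1.84-fold higher. EGR1, MITF and TYR changed by -0.86, -0.64 and -0.47. S100A1, IL32, C15orf54, MYEOV, the matrix protein gene TGFBI and LDLRAD4 rose by 2.21 to 3.22. CD177 (0.0424 ± 0.0201 against 44.7 ± 0.158 CPM), the selenium carrier SEPP1, the mucin MUC5AC, SCUBE1, COLEC12 and ITGA8 changed by -9.92, -8.24, -7.82, -6.40, -5.55 and -5.03.

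All 20 G1/S genes rose, also adjusted over the list alone (adjusted p = 1.08e-19), with CDC6 at 1.03 and RRM2 at 0.91. Of 20 G2/M genes 19 rose (20 adjusted over the list alone, adjusted p = 2.92e-18), with UBE2C at 1.14 and AURKB at 1.23. Interferon-response genes fell in 15 of 19 (16 adjusted over the list alone, adjusted p = 9.41e-09), with IFIT1 at -2.38 and IFIT2 at -1.41. Class II genes fell in 7 of 8, the same adjusted over the list alone (adjusted p = 6.52e-08), with HLA-DRA at -2.45 and CD74 at -1.59. Class I genes fell in 11 of 14 (13 adjusted over the list alone, adjusted p = 7.10e-07, adjusted p = 0.0512 with an estimated correlation), with HLA-C at -0.71 and NLRC5 at -0.91. Melanocyte genes fell in 12 of 19 and rose in 1 (12 and 2 adjusted over the list alone, adjusted p = 2.37e-05), with DCT at -3.75, SLC45A2 at -1.47 and SOX10 rising by 0.62. Neural crest genes rose in 6 of 14 and fell in 2 (7 and 2 adjusted over the list alone, adjusted p = 0.0179), with NES at 0.92, CDH19 at 0.87 and ITGA4 at -0.89. ATF4 targets rose in 15 of 18 and fell in 1, the same adjusted over the list alone (adjusted p = 3.89e-08), with ATF3 at 0.88, XBP1 at 0.78 and DDIT4 at -0.84. Ribosome biogenesis rose in 10 of 18 and fell in 1 (11 and 1 adjusted over the list alone, adjusted p = 1.44e-04), with DKC1 at 0.51 and NOP56 at 0.47. Fibroblast markers fell in 6 of 10 and rose in 1, the same adjusted over the list alone (adjusted p = 0.00847), with POSTN at -3.74, COL3A1 at -2.39 and COL6A3 rising by 2.07.

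ERK output rose in 12 of 23 and fell in 6 (13 and 7 adjusted over the list alone) and did not pass (adjusted p = 0.0553, adjusted p = 0.255 with an estimated correlation) except with DESeq2 statistics (adjusted p = 0.012), no count filter (0.0118), the 4 libraries that stood apart left out (0.0407) or fry (1.26e-04), or without week 3 continuous replicate 1 (0.036) or rechallenged replicate 1 (0.0477) or 2 (0.0323). Invasive-state genes moved both ways between these arms, 8 of 20 up and 5 down (9 and 5 adjusted over the list alone, adjusted p = 0.0148, adjusted p = 0.104 with an estimated correlation), with PDGFRB at -1.91. Secreted factors rose in 9 of 17 and fell in 4, the same adjusted over the list alone (adjusted p = 0.0123, adjusted p = 0.179 with an estimated correlation), with LIF at 1.22, HBEGF at 1.66 and STC1 at -2.26, a call lost with the 4 libraries that stood apart left out (adjusted p = 0.0941). Cholesterol synthesis rose in 7 of 19 and fell in 2, the same adjusted over the list alone (adjusted p = 0.00529, adjusted p = 0.114 with an estimated correlation), with HMGCS1 at 0.51. Lysosome genes fell in 9 of 20 (13 adjusted over the list alone, adjusted p = 2.15e-05, adjusted p = 0.207 with an estimated correlation), with CTSA at -0.85 and CTSB at -0.43. Glycolysis fell in 9 of 21 and rose in 4 (10 and 5 adjusted over the list alone, adjusted p = 0.0406, adjusted p = 0.368 with an estimated correlation), with adrenomedullin (ADM) at -1.14, ALDOC at -1.87 and PFKP rising by 0.56. That call was lost without week 3 continuous replicate 2 (adjusted p = 0.0885) or 3 (adjusted p = 0.0777) or rechallenged replicate 2 (adjusted p = 0.0913) or 3 (adjusted p = 0.0776), or with DESeq2 statistics (adjusted p = 0.0566). Replicate 1 of each arm stood apart from its group in chi-square per gene (38.1 and 43.2 rechallenged, 25.2 and 21.5 continuous), and rechallenged replicate 1 had the lowest MKI67 of its group (167 against 235 and 249 CPM). Its G2/M list was not lower, at a mean log2 CPM of 6.58 against 6.49 and 6.47. Back on drug, 2874 genes were higher and 2940 lower than under continuous drug, 604 and 1004 at least 2-fold.

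**Figure D3:**
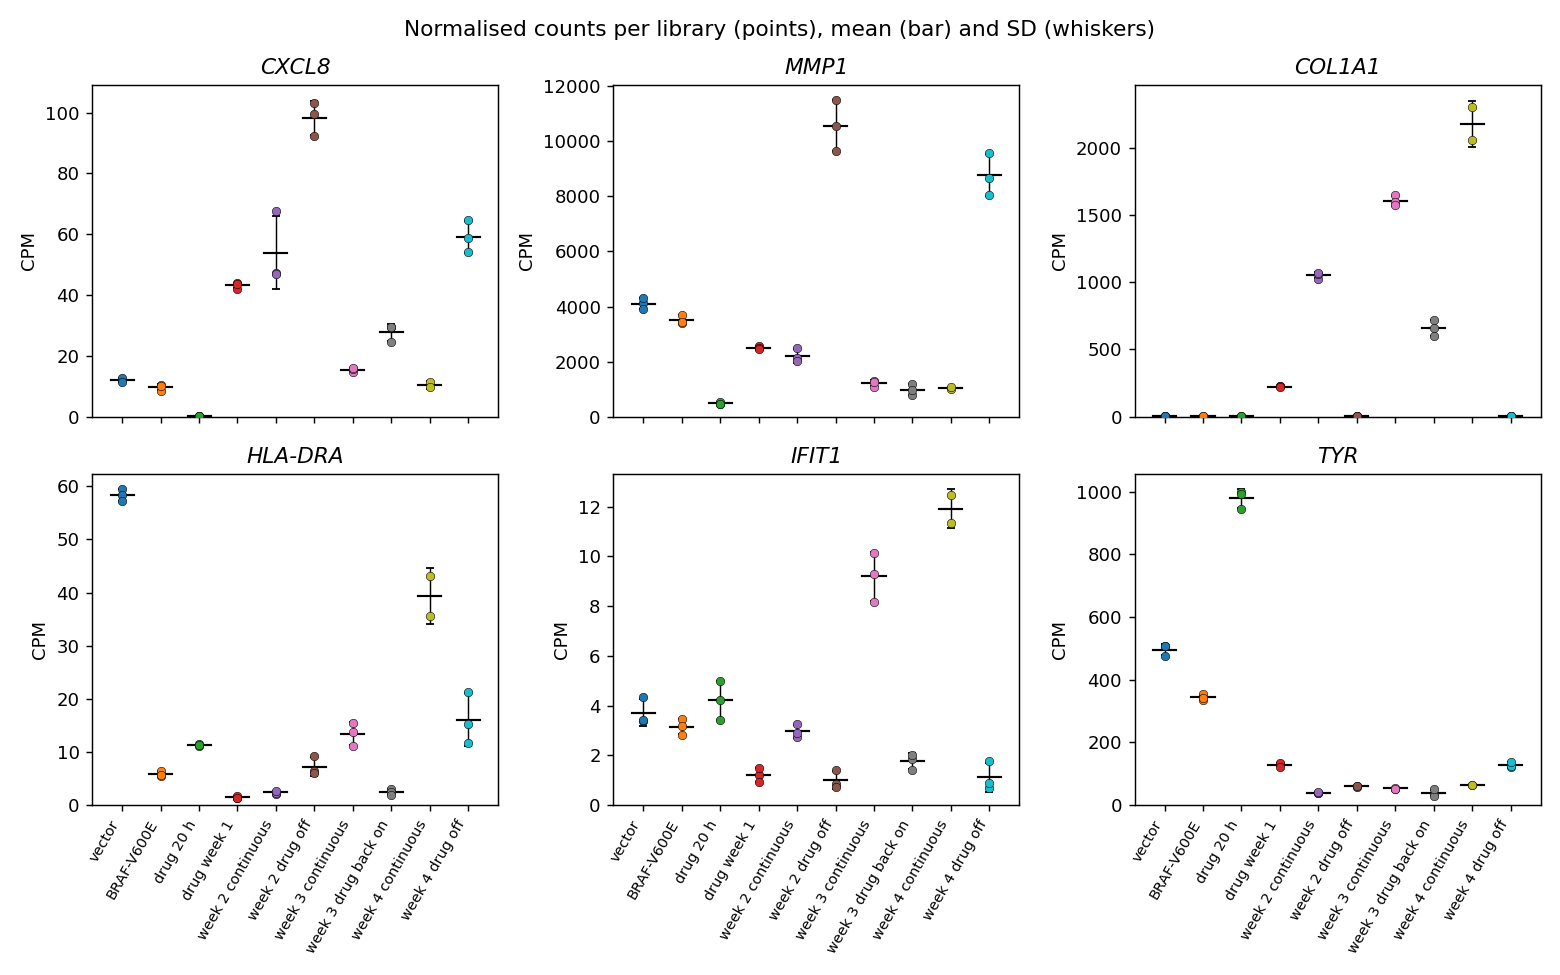
CPM of CXCL8, MMP1, COL1A1, HLA-DRA, IFIT1 and TYR in each library (points) with group mean (bar) and SD (whiskers), groups along the horizontal axis. COL1A1 reaches a mean of 2179 CPM after 4 weeks of continuous drug and is at 4.95 CPM off drug at that week.

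The sixth comparison asked the same of the second week off drug, at week 4. BRAF was 3.35-fold higher off drug (3404 ± 83.9 CPM, SD, n = 3, against 1018 ± 39.1, n = 2; log2 1.74 ± 0.09 SE, adjusted p = 2.48e-16). ETV4 was 17.9-fold, SPRY4 10.2-fold, DUSP6 4.24-fold and CCND1 3.02-fold higher, and MITF rose by 1.82, AXL by 1.34, FOSL1 by 1.11 and TYR by 1.01. MKI67 rose by 0.95 (SE 0.24, adjusted p = 0.00115), against a continuous arm whose cell cycle genes had fallen. Mean log2 CPM of the G2/M list under continuous drug was 6.46 to 6.58 at week 2, and 5.23 and 5.24 at week 4. Off drug it was 4.84 to 5.1, then 5.63 to 5.79. Against the on-drug sample before each withdrawal, the G2/M median changed by -0.86 and then by -0.75. EGR1 fell by 0.41 (adjusted p = 0.00538), a call lost without week 4 continuous replicate 2 (-0.27, adjusted p = 0.151). CDKN1A rose by 0.23 (adjusted p = 0.0164), lost without continuous replicate 1 (0.0801) or 2 (0.0876). PAEP, the lipase PLA2G7 and NPR1 rose by 8.76, 8.31 and 8.19. LCN1, IL36RN and the keratin KRT6A had 3, 1 and 3 counts on drug, at ratios of 829 (95% counting interval 284 to 4022), 652 (117 to 25760) and 353 (121 to 1714). SEPP1 was 923-fold lower, COL1A1 440-fold, COL3A1 434-fold, EFEMP1 360-fold and MUC5AC 358-fold lower, and the smooth muscle coactivator MYOCD kept 2 counts against 975, a ratio of 710 (196 to 5872).

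Of 23 ERK output genes 19 rose and 3 fell, the same adjusted over the list alone (adjusted p = 7.40e-12), with DUSP5 at 4.38 and SPRY1 at -1.03. Secreted factors rose in 13 of 17 and fell in 3, the same adjusted over the list alone (adjusted p = 9.53e-08), with LIF at 4.25, IL11 at 5.02 and IL6 at -4.83. Interferon-response genes fell in 17 of 19, the same adjusted over the list alone (adjusted p = 9.53e-08), with BST2 at -5.78 and STAT2 at -1.25. Ribosome biogenesis rose in 16 of 18, the same adjusted over the list alone (adjusted p = 2.01e-05), with DKC1 at 0.78 and RRP12 at 0.79. Fibroblast markers fell in 7 of 10 and rose in 2, the same adjusted over the list alone (adjusted p = 5.86e-04), with COL6A3 rising by 3.41. G1/S genes rose in 19 of 20, the same adjusted over the list alone (adjusted p = 9.53e-08, adjusted p = 0.0541 with an estimated correlation), with CDC6 at 1.54 and CDC25A at 1.89. G2/M genes rose in 17 of 20 and fell in 1 (19 and 1 adjusted over the list alone, adjusted p = 4.66e-04, adjusted p = 0.306 with an estimated correlation), with AURKB at 1.14, UBE2C at 0.92 and KIF20A at -0.53. Class I genes fell in 12 of 14, the same adjusted over the list alone (adjusted p = 8.57e-05, adjusted p = 0.188 with an estimated correlation), with PSMB9 at -1.99. Immediate early genes fell in 10 of 15 and rose in 5, the same adjusted over the list alone (adjusted p = 0.0274, adjusted p = 0.35 with an estimated correlation), with CYR61 at -3.65, FOS at -3.29 and EGR3 rising by 4.32. Of the 4 tested leukocyte and endothelial markers 3 rose, LYZ from 0.302 to 9.31 CPM. Epithelial markers had a mean log2 CPM of 2.29 to 2.61 per library off drug, and 1.56 and 1.67 on drug. The counts were 5345 higher and 5144 lower, 2275 and 2438 at least 2-fold. Both withdrawals changed many genes alike: 3522 were higher in both (1460 expected) and 3189 lower in both (1436 expected), 910 went opposite ways (2897 expected), and log2 changes correlated across genes at r = 0.75 (rho 0.6), genes not being independent replicates.

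The seventh comparison asked how far cells a week off drug were from cells never treated. BRAF was 3.61-fold above untreated cells (3232 ± 59.9 against 895 ± 7.17 CPM, SD, n = 3; adjusted p = 8.78e-19). DUSP6 was up by 0.64, SPRY4 down to 914 ± 108 from 1348 ± 54.6 CPM and ETV4 at -0.28. CCND1 (0.07, adjusted p = 0.304, with 0.0382 by DESeq2 and up to 0.81 over the alternatives) and EGR1 (-0.02, 0.902) did not pass. Cell identity had not come back, with MITF 10-fold lower, TYR 5.75-fold lower and AXL 19.6-fold higher (71.3 ± 2.48 against 3.61 ± 0.59 CPM). MKI67 was 3.17-fold lower, CDKN1A 3.05-fold higher and FOSL1 3.33-fold higher. The chemerin receptor CMKLR1, TRIM54, the T-bet gene TBX21 and KCNK1 had no count in untreated cells and were at least 766-, 905-, 302- and 287-fold higher, and IL36RN and GALNT9 had 1 count, at ratios of 3818 (685 to 150800) and 3273 (587 to 129300). PLN, POSTN, the serotonin receptor HTR2B, TUBB4A, the fatty acid binder FABP7 and COL14A1 changed by -9.08, -7.43, -6.84, -6.41, -5.93 and -5.69.

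All 17 secreted factors rose, also adjusted over the list alone (adjusted p = 2.64e-11), with IL11 at 7.16 and STC1 at 6.74. Class I genes rose in all 14, also adjusted over the list alone (adjusted p = 4.75e-08), with the peptide transporter TAP1 at 2.69 and TAPBP at 1.18. Invasive-state genes rose in 16 of 20 and fell in 2, the same adjusted over the list alone (adjusted p = 1.09e-08), with NT5E at 3.53 and LOXL2 at -0.51. Neural crest genes rose in 10 of 14 and fell in 3, the same adjusted over the list alone (adjusted p = 0.00156), with NGFR at 3.92, GFRA2 at 5.57 and RXRG at -0.92. Melanocyte genes fell in 14 of 19 and rose in 3, the same adjusted over the list alone (adjusted p = 5.10e-07), with SLC45A2 at -4.33, PMEL at -4.02, and OCA2 at 35 counts against 2, a ratio of 17.9 (4.59 to 153). G2/M genes fell in all 20 and G1/S genes in 19 of 20 (all 20 in both adjusted over the list alone, adjusted p = 9.87e-14 and 6.45e-12), with CCNA2 at -2.23, KIF20A at -1.51, MCM6 at -2.09 and MCM3 at -1.72. Cholesterol synthesis fell in 17 of 19 and rose in 1, the same adjusted over the list alone (adjusted p = 4.75e-08), with DHCR7 at -2.42 and SREBF2 at -1.68. Receptor tyrosine kinases rose in 13 of 20 and fell in 5, the same adjusted over the list alone (adjusted p = 0.00566, adjusted p = 0.156 with an estimated correlation), with FGFR1 at 3.95, EPHB2 at 3.70 and ROR1 at -3.07, and a median of 1.18, or 0.87 with ROR2 at its bound. Oxidative phosphorylation fell in 14 of 24 (15 adjusted over the list alone, adjusted p = 0.00159, adjusted p = 0.34 with an estimated correlation), with PPARGC1A at -3.53 and ATP5C1 at -0.92. Lysosome genes rose in 17 of 20 and fell in 1, the same adjusted over the list alone (adjusted p = 7.86e-05, adjusted p = 0.256 with an estimated correlation), with SQSTM1 at 2.29, CTSB at 1.49 and CTSK at -1.59. ATF4 targets rose in 14 of 18 and fell in 1, the same adjusted over the list alone (adjusted p = 1.34e-05, adjusted p = 0.106 with an estimated correlation), with DNAJB9 at 2.77 and ATF3 at 2.87. Ribosome biogenesis fell in 15 of 18 and rose in 1 (16 and 2 adjusted over the list alone, adjusted p = 5.11e-04, adjusted p = 0.0679 with an estimated correlation), with NCL at -0.89, POLR1B at -1.12 and RRP12 rising by 0.62. ERK output rose in 14 of 23 and fell in 7 (14 and 8 adjusted over the list alone) and did not pass (median 0.64, adjusted p = 0.106, adjusted p = 0.34 with an estimated correlation) except with DESeq2 statistics (adjusted p = 0.0219), no count filter (0.0305) or fry (4.55e-10). Epithelial markers rose in 5 of 7 and fell in 1, the same adjusted over the list alone, and did not pass (median 1.99, adjusted p = 0.155) except with fry (1.06e-09). All 4 tested leukocyte and endothelial markers rose, PECAM1 from 0.0631 to 2.78 CPM. The test counted 6388 genes higher and 5905 lower, 3525 and 2322 at least 2-fold. Changes on withdrawal and changes by BRAF-V600E without drug shared 775 higher genes (394 expected) and 935 lower genes (568 expected), 866 were opposite (958 expected), and r across genes was 0.22 (rho 0.15).

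The eighth comparison set the second week of exposure (week 3, on drug) against the first (week 1), both ending in 7 days of drug. Time in the course differs between these groups too. By week 3 of continuous drug EGR1, class I and interferon-response genes had also risen against week 1, and ATF4 targets had fallen. G1/S genes had fallen there instead of rising. At week 2 of continuous drug, however, they stood close to the rechallenged cells. Mean log2 CPM per library was 5.42 to 5.59 against 5.48 to 5.65, and 5.16 to 5.18 at week 1. The same held for G2/M (6.46 to 6.58 against 6.47 to 6.58) and invasive-state genes (6.28 to 6.5 against 6.32 to 6.56). The rise of these lists is thus shared with the continuous arm at week 2. Changes that both arms share cannot be credited to the second exposure alone. The immediate early genes EGR1, FOS and FOSB were higher the second time, EGR1 17.2-fold (159 ± 6.41 against 9.23 ± 0.56 CPM, SD, n = 3), FOS 16.7-fold and FOSB 11.2-fold. Of the 15 in their list 7 rose and 5 fell (7 and 6 adjusted over the list alone), and the list did not pass (median 0.18, adjusted p = 0.137) except with DESeq2 statistics (adjusted p = 1.91e-06) and fry (4.83e-07). AXL was 2.46-fold and DUSP6 1.7-fold higher, ETV4 rose by 0.76 and FOSL1 by 0.36. Pigment-cell genes were lower still, with TYR 3.34-fold, PMEL 9.6-fold and MLANA 7.88-fold lower. MKI67 rose by 0.83 (SE 0.21, adjusted p = 0.0021). MITF rose by 0.51 (adjusted p = 0.00255) and BRAF by 0.31 (0.00232), calls lost without rechallenged replicate 3 (0.0655 and 0.0716). CDKN1A fell by 0.21 (0.0199), lost without week 1 replicate 2 (0.109) or rechallenged replicate 2 (0.0589) or 3 (0.0584). SPRY4 (-0.13, 0.286) and CCND1 (-0.06, 0.507) did not pass. CACNA2D3, TENM2 and SDK1 rose by 3.65, 3.54 and 3.50, and HTR2B, the lipid carrier APOE, SOX8 and AKR1C1 changed by -4.18, -3.22, -2.86 and -2.80.

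G2/M genes rose in 19 of 20, the same adjusted over the list alone (adjusted p = 2.52e-14), with KIF20A at 1.00 and TPX2 at 0.84. Invasive-state genes rose in 12 of 20 and fell in 2, the same adjusted over the list alone (adjusted p = 1.25e-06), with TCF4 at 2.16, WNT5A at 1.56 and SLIT2 at -0.59. Cholesterol synthesis rose in 14 of 19 (15 adjusted over the list alone, adjusted p = 2.37e-09), with STARD4 at 1.35. ATF4 targets fell in 15 of 18 (16 adjusted over the list alone, adjusted p = 2.71e-11), with TRIB3 at -1.64 and SESN2 at -0.91. Melanocyte genes fell in 11 of 19 and rose in 4 (12 and 5 adjusted over the list alone, adjusted p = 8.58e-05, adjusted p = 0.0656 with an estimated correlation), with RAB27A rising by 0.62. G1/S genes rose in 16 of 20 (17 adjusted over the list alone, adjusted p = 1.83e-06, adjusted p = 0.0656 with an estimated correlation), with CDC6 at 0.61 and RRM2 at 0.54. Class I genes rose in 12 of 14, the same adjusted over the list alone (adjusted p = 1.25e-06, adjusted p = 0.0656 with an estimated correlation), with HLA-B at 1.29 and TAPBP at 0.50. Class II genes rose in 6 of 8, the same adjusted over the list alone (adjusted p = 3.24e-05, adjusted p = 0.0651 with an estimated correlation), with CTSS at 1.85 and HLA-DMA at 1.73. Lysosome genes fell in 15 of 20 and rose in 1 (16 and 1 adjusted over the list alone, adjusted p = 1.84e-10, adjusted p = 0.0656 with an estimated correlation), with HEXA at -0.76, WIPI1 at -0.73 and CTSK rising by 0.51. Epithelial markers rose in 5 of 7 and fell in 1 (6 and 1 adjusted over the list alone, adjusted p = 0.0171, adjusted p = 0.0579 with an estimated correlation), with desmoplakin (DSP) at 1.94, KRT18 at 0.60 and ESRP1 at -1.28. Interferon-response genes rose in 9 of 19 and fell in 2 (10 and 3 adjusted over the list alone, adjusted p = 0.0428, adjusted p = 0.282 with an estimated correlation), with OAS2 at 2.38, OAS3 at 1.01 and STAT2 at -0.50. That call was lost without week 1 replicate 1 (0.0546) or 2 (0.0536) or rechallenged replicate 1 (0.0511) or 3 (0.06), or with the 4 libraries that stood apart left out (0.065). In all 3392 genes were higher and 2979 lower, 1227 and 565 at least 2-fold.

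The ninth comparison tested whether cells answered the second exposure (week 2 off drug to week 3 on) otherwise than the first (untreated to week 1). Proliferation genes answered in opposite ways: MKI67 fell by 1.06 the first time and rose by 1.43 the second, a difference of 2.49 ± 0.29 (SE, 3 libraries in each of 4 groups, adjusted p = 2.05e-08). MITF fell by 4.94 and then by 1.09 (difference 3.84), EGR1 by 5.51 and then 1.38 (4.12), and AXL rose by 3.99 and then by 1.00 (-2.99). BRAF fell by 0.18 and then by 1.73 (-1.55 ± 0.11, adjusted p = 3.27e-13), having started from 895 CPM the first time and 3232 the second. DUSP6 fell about as much both times, a difference of 0.12 that did not pass (0.282), nor did CCND1 (-0.13, 0.213, with 0.0454 by DESeq2 and up to 0.717 over the alternatives). SPRY4 (0.43), ETV4 (1.04) and TYR (0.78) fell less the second time, FOSL1 rose less (-1.37), and CDKN1A rose by 1.24 and then fell by 0.59 (-1.82). The largest positive differences were those of SLC5A4, GPRC5B, FABP7, POSTN, DCT and QPRT, from 5.12 to 6.84. FABP7 went from 679 to 4.77 CPM the first time and from 11.1 to 3.87 the second. The SLC5A4 difference (6.84 ± 1.88, adjusted p = 0.00319) was lost without rechallenged replicate 3 (5.97, 0.101), and this gene had 1 count at week 1. Negative differences were largest for TRIM54, the steroid reductase AKR1C1, CMKLR1, CYP4F3, GALNT9 and ZNF804A, from -13.39 to -9.51. AKR1C1 went from 0.154 to 23.2 CPM and then from 47.0 to 3.32. TRIM54 and CMKLR1 had no count in untreated cells and GALNT9 had 1 count, so their fitted differences are no bound.

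G2/M genes were shifted upwards in all 20 and G1/S genes in all 20, also adjusted over the list alone (adjusted p = 3.48e-19 and 1.57e-15), the G2/M median going from -0.74 on first exposure to 1.56 on the second. KIF20A differed by 2.50, TPX2 by 2.25, TYMS by 2.36 and MCM3 by 1.96. Cholesterol synthesis shifted up in 18 of 19, the same adjusted over the list alone (adjusted p = 1.88e-12), with DHCR7 at 3.01. Secreted factors shifted down in 16 of 17, the same adjusted over the list alone (adjusted p = 6.03e-11), having risen by a median of 2.14 and then fallen by 2.17, with IL11 at -6.51 and STC1 at -6.21. Invasive-state genes shifted down in 13 of 20 and up in 4, the same adjusted over the list alone (adjusted p = 1.95e-05), with NT5E at -2.66. Neural crest genes shifted down in 9 of 14 and up in 3, the same adjusted over the list alone (adjusted p = 3.65e-04), with NGFR at -4.56 and NES at -2.03. ATF4 targets shifted down in 16 of 18 and up in 1, the same adjusted over the list alone (adjusted p = 5.53e-10), with DNAJB9 at -3.25 and SESN2 at -2.97. The melanocyte list shifted up in 13 of 19 and down in 3, the same adjusted over the list alone (adjusted p = 0.00112, adjusted p = 0.109 with an estimated correlation), with SLC45A2 at 3.19 and TYRP1 at -3.54. RAF-MEK-ERK components shifted down in 7 of 16 and up in 2, the same adjusted over the list alone (adjusted p = 0.0379, adjusted p = 0.0757 with an estimated correlation), with MAP2K1 at -1.04 and MAPK3 at 0.44. That call was lost without week 2 off-drug replicate 2 (0.0502) or 3 (0.0522), or with the 4 libraries that stood apart left out (0.0528). Receptor tyrosine kinases shifted down in 11 of 20 and up in 2, the same adjusted over the list alone (adjusted p = 0.00316, adjusted p = 0.123 with an estimated correlation), with FGFR1 at -2.88, PDGFRA at -3.37 and ROR1 at 4.22. Class I genes shifted down in 10 of 14 (12 adjusted over the list alone, adjusted p = 1.74e-04, adjusted p = 0.125 with an estimated correlation), with HLA-E at -1.56 and TAP1 at -2.27.

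Class II genes shifted up in 6 of 8 and down in 1, the same adjusted over the list alone (adjusted p = 0.0118, adjusted p = 0.206 with an estimated correlation), with CTSS at 2.87 and CIITA at -0.88, a call lost with the 4 libraries that stood apart left out (adjusted p = 0.0528). Oxidative phosphorylation shifted up in 9 of 24, the same adjusted over the list alone (adjusted p = 0.00741, adjusted p = 0.472 with an estimated correlation), with PPARGC1A at 4.10 and UQCRC2 at 0.83, a call lost in the same way (adjusted p = 0.0708). Lysosome genes shifted down in 17 of 20 and up in 1, the same adjusted over the list alone (adjusted p = 3.86e-09, adjusted p = 0.0991 with an estimated correlation), with SQSTM1 at -2.87 and WIPI1 at -2.09. Ribosome biogenesis shifted up in 14 of 18 and down in 2, the same adjusted over the list alone (adjusted p = 0.00128, adjusted p = 0.097 with an estimated correlation), with DKC1 at 0.89 and RRP12 at -0.72. The difference passed for 4782 genes upwards and 5116 downwards, 2342 and 2844 of them at least 2-fold. Both exposures shared 2453 higher genes (1566 expected) and 2297 lower genes (1557 expected), 2678 went opposite ways (3124 expected), and r across genes was 0.39 (rho 0.26). The BCL2 family list, of cell death regulators, was not called by camera with the preset correlation in any of the 17 comparisons. At week 2 of continuous drug against week 1 it passed with DESeq2 statistics (adjusted p = 0.0316), no count filter (0.00625), the 4 libraries that stood apart left out (0.0362), fry (1.14e-06), or without week 1 replicate 2 (0.0495) or 3 (0.0433) or week 2 continuous replicate 3 (0.0248), and fry passed it in 11 other comparisons. At week 1 against untreated cells 2 of its 13 tested genes rose and 4 fell (median -0.12, adjusted p = 0.443). The list of p53 targets and CDK inhibitors was not called by camera in these 9 comparisons, though fry passed it in 6 of them, with 6 of 17 higher and 4 lower at week 1 (median 0.17, adjusted p = 0.756).

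**Figure D4:**
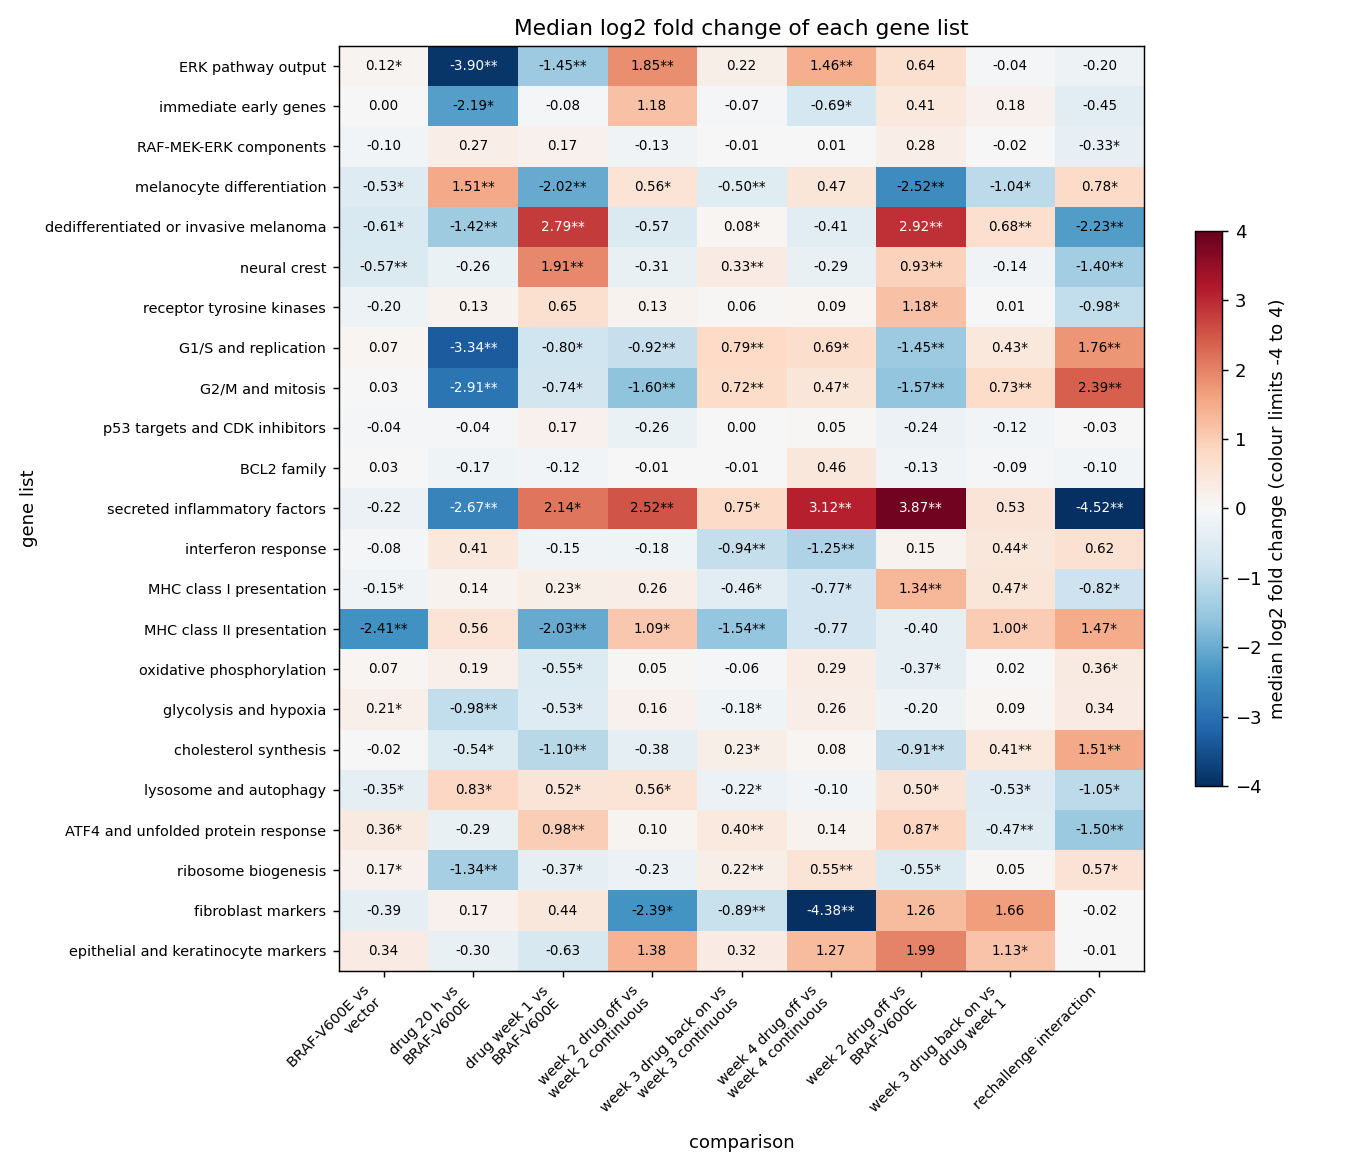
Median log2 fold change of each gene list (vertical axis) in the 9 comparisons (horizontal axis), with 1 star for lists called with the preset correlation and 2 for those called with the estimated correlation too. The G2/M list goes from -0.74 on first exposure to a difference of 2.39 in the last column.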

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

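Of the tests in this part, 4 were chosen only after the result was seen: the fall of BRAF on rechallenge, the COL1A2 share, the invasive-state list and the ERK output list at week 4. The first 2 results that follow stood out because an effect differed between a first and a second exposure, or between a first and a second withdrawal, by a test of the difference itself. The rise of BRAF, the fibroblast markers and the immediate early genes, further down, were picked on reading the results.

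The response to a second week of drug differed from the first for 4782 genes upwards and 5116 downwards. Among the 12 fixed genes the differences in log2 change were BRAF -1.55, SPRY4 0.43, ETV4 1.04, FOSL1 -1.37, EGR1 4.12, MITF 3.84, TYR 0.78, AXL -2.99, MKI67 2.49 and CDKN1A -1.82. The genes with the largest differences were SLC5A4 6.84, GPRC5B 5.85, FABP7 5.63, POSTN 5.22, DCT 5.15 and QPRT 5.12 upwards, and TRIM54 -13.39, AKR1C1 -10.98, CMKLR1 -10.62, CYP4F3 -10.44, GALNT9 -9.75 and ZNF804A -9.51 downwards. TRIM54 and CMKLR1 had no count and GALNT9 had 1 count in untreated cells, so their values and ranks are uncertain. SLC5A4 did not pass without week 3 rechallenged replicate 3 (5.97, adjusted p = 0.101). Medians of list differences were G2/M 2.39, G1/S 1.76, cholesterol synthesis 1.51, MHC class II 1.47, melanocyte 0.78, ribosome biogenesis 0.57, oxidative phosphorylation 0.36, RAF-MEK-ERK components -0.33, MHC class I -0.82, receptor tyrosine kinases -0.98, lysosome -1.05, neural crest -1.40, ATF4 targets -1.50, invasive state -2.23 and secreted factors -4.52. With an estimated correlation 8 of these 15 did not pass: class II (adjusted p = 0.206), melanocyte (0.109), ribosome biogenesis (0.097), oxidative phosphorylation (0.472), RAF-MEK-ERK components (0.0757), class I (0.125), receptor kinases (0.123) and lysosome (0.0991). Of 100 drawn splits of these 12 libraries, 1, the real one, gave as many calls (9898, highest other 7223). These splits mix groups that differ strongly in any case, drug and no drug among them, so they do not show whether chance is excluded for the difference. A split with 7223 calls points to that structure of the samples. The first exposure started from untreated cells and the second from cells 14 days into the course, so starting state and time differ between them.

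The second withdrawal differed from the first for 1557 genes upwards and 1947 downwards. Differences were DUSP6 -0.87, ETV4 -0.91, CCND1 -0.37, EGR1 -4.14, MITF 0.88, TYR 2.85 and AXL -1.25. List medians were melanocyte 1.63, G1/S 0.23 (adjusted p = 0.00316, adjusted p = 0.322 with an estimated correlation), ribosome biogenesis 0.16 (adjusted p = 0.0222, adjusted p = 0.27 with an estimated correlation), cholesterol synthesis -0.53, interferon response -0.57, invasive state -0.71 and MHC class I -1.02. Of 100 drawn splits of the 12 libraries, 9 gave as many calls as the real one, itself included (3504, highest other 6793). Splits with more calls point to differences by drug, so this count too does not show whether chance is excluded.

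For 13 comparisons of 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each 1 split, the real one, gave as many calls. Real counts with 0 as the highest other were 3476 (BRAF-V600E against vector), 11003 (20 hours against untreated), 11098 (week 1 against untreated), 5814 (week 3 rechallenged against continuous), 12293 (week 2 off drug against untreated) and 11830 (week 1 against 20 hours). The same held for 6055 and 7973 (weeks 2 and 3 continuous against week 1), 11010 (week 4 off drug against untreated) and 11536 (week 3 rechallenged against week 2 off drug). Week 2 off drug against continuous gave 11318 (highest other 982), week 3 rechallenged against week 1 6371 (highest other 1) and the later against the earlier withdrawal 5944 (highest other 1). Comparisons with week 4 under continuous drug, with 2 libraries, had no splits counted.

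BRAF stood 3.61-fold above untreated cells after a week off drug. Scaling is argued against by a fold of 3.737 with RLE factors. The sum of BRAF and its pseudogene BRAFP1 rose 3.609-fold, but BRAFP1 held too few counts beside BRAF in untreated cells to alter that fold. Reads moved from BRAFP1 to BRAF are argued against by those few counts, while new BRAFP1 transcripts counted as BRAF stay open. Lasting selection of cells with more BRAF stays open. BRAF changed by -1.73 when drug returned, but drug state changed at the same time and the drug may itself lower BRAF counts. Release from the drug may raise BRAF counts reversibly, a hypothesis found and tested on the same data, and whether added or native BRAF rose stays open because counts per gene do not part them.

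Fibroblast markers were higher after 4 weeks of continuous drug than at week 1 in 8 of 10, the same adjusted over the list alone (median 2.19, adjusted p = 6.74e-05), with COL1A1 at 2179, COL3A1 at 39.8, LUM at 51.3, DCN at 1.63 and FAP at 126 CPM. That median is 2.06 with PDPN and THY1, which had no count at week 1, at their bounds. A cell line is not expected to hold admixed fibroblasts. As the source of most COL1A1 they are argued against by COL1A2, their partner chain of COL1A1, at 1.248% of COL1A1 (27.2 CPM). That share does not speak to the other markers, because COL1A1 from another source would lower it whether or not fibroblasts were present. DCN plus LUM, at 2.429% of COL1A1, lay between the bounds set for that test. Admixed fibroblasts as a source of the other markers stay open. Whether the invasive-state program rose over the same interval stays open, since 7 of its 20 genes rose and 8 fell (median 0.12). A change of matrix genes within the melanoma cells could be the source, as a hypothesis.

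Immediate early genes were higher after 4 weeks of continuous drug than at week 1, EGR1 by 5.86 and FOS by 5.84. Of the 15 in the list 10 rose and 4 fell (11 and 4 adjusted over the list alone, adjusted p = 1.61e-04, adjusted p = 0.0834 with an estimated correlation). A heat shock response at harvest is argued against by 12 stress genes, mostly of heat shock, with a median of -0.35 (1 rose, 8 fell). The gene that rose was SOCS3, by 1.37. Other stress at harvest, which these genes hardly cover, stays open. A return of ERK output stays open, since 7 of 23 genes of its list rose and 8 fell (median -0.08). What raised these genes stays open, and no biological explanation was tested further.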

How the results depend on the processing

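Leaving out together the 4 libraries that stood apart from their group was the test in this part chosen only after the data were seen. All 68 counts of genes past the threshold stayed within 1.5 times their reported values with DESeq2, RLE factors, no count filter, the libraries of the compared groups alone, a replicate term, and the 4 libraries left out. Leaving out 1 library at a time, all 448 counts stayed within that limit, the largest ratio being 1.423, for genes lower in BRAF-V600E against vector cells (1429 against 2034, without vector replicate 1). Genes higher there ran from 1029 to 1318, against 1442.

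For week 3 rechallenged against continuous, 69.3% of the calls were shared when the compared groups alone entered the fit (4031 of 5814, with 4059 calls there), and 74.5% (4329) with the 4 libraries left out, with 5484 calls there.

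Of the results of named genes, each for 1 gene in 1 comparison, 739 kept their side of the threshold and direction with DESeq2 (2 stronger, 3 weaker), 740 with no count filter (4 weaker), 736 with the compared groups alone (4 weaker), 741 with the replicate term or RLE factors (3 weaker each) and 740 with the 4 libraries left out (4 weaker). Over single libraries left out, 4845 stayed the same, 43 became weaker and 1 stronger.

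With the correlation between genes estimated per list, 304 list results stayed the same and 87 were no longer past the threshold. With DESeq2 statistics 357 stayed the same, 26 became stronger and 8 weaker. Without a count filter 352 stayed and 39 became stronger, with RLE factors 389 stayed and 2 became stronger, and with the replicate term all 391 stayed. With the 4 libraries left out 370 stayed, 14 became stronger and 7 weaker, and over single libraries left out 2515 stayed, 45 became stronger and 16 weaker. Fry tests whether a list changed at all, while camera tests it against the other tested genes, so a stronger fry call answers another question. With fry, 257 stayed, 130 became stronger and 4 reversed, none of the 4 called by camera: immediate early genes in BRAF-V600E against vector cells (0.0474), neural crest at 20 hours against untreated (0.0374), RAF-MEK-ERK components off drug against continuous at week 2 (0.022), and immediate early genes in week 3 rechallenged against week 2 off drug (0.00252). The cause was not tested. The 3 overlaps stayed within 1.5 times their reported values with DESeq2, RLE factors, no count filter, the replicate term, the 4 libraries left out, and in all 35 cases with 1 library left out. Genes changed alike by both withdrawals (6711) ran from 5778 to 6856, those by withdrawal and BRAF-V600E (1710) from 1345 to 2260, and those by both exposures (4750) from 4469 to 4766.

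The replicate numbers do not pair the samples, so no comparison was treated as paired. On simulated data at one depth and group size 38.8% of 1.5-fold changes were recovered, and 77.3% of 4-fold changes. Depth was not varied.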

Other observations

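No test in this part was chosen after the result was seen. From 20 hours to 7 days of drug, ERK targets rose, CCND1 by 3.96 on the log2 scale, SPRY4 by 3.68, DUSP6 by 2.54 and FOSL1 by 5.32, the last to above its level in untreated cells. ERK output rose in 19 of 23 genes and fell in 3 (19 and 4 adjusted over the list alone, adjusted p = 7.26e-12). MITF fell by 5.99 and AXL rose by 6.56, with melanocyte genes down in 17 of 19 (adjusted p = 8.69e-14) and invasive-state genes up in 18 of 20 (19 adjusted over the list alone, adjusted p = 1.80e-13). Cell cycle lists came back up, G1/S in 19 of 20 (adjusted p = 1.33e-16) and G2/M in all 20 (adjusted p = 9.23e-16), and secreted factors rose in 15 of 17 (adjusted p = 2.17e-10), with CXCL8 at 7.88. In all 5856 genes were higher and 5974 lower.

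Along the continuous arm, COL1A1 rose against week 1 by 2.24 ± 0.13, 2.84 ± 0.14 and 3.28 ± 0.14 (SE) at weeks 2, 3 and 4, and LUM by 2.64, 4.21 and 5.24. EGR1 rose by 2.39, 4.97 and 5.86 and DUSP6 by 0.27, 0.68 and 1.18, while CCND1 fell by 0.42, 1.40 and 1.47. AXL rose by 1.03 at week 2 and fell by 0.61 and 0.99 at weeks 3 and 4. Class II genes rose in 6 of 8 at week 2 (adjusted p = 6.62e-05, adjusted p = 0.053 with an estimated correlation) and in all 8 at weeks 3 and 4 (adjusted p = 2.81e-10 and 6.93e-12), with HLA-DRA at 4.73 at week 4. Class I genes rose in 12, 14 and 14 of 14 (adjusted p = 5.83e-09, 1.37e-11 and 3.13e-12), with HLA-B at 1.28, 2.05 and 2.77. Interferon-response genes rose in 11, 15 and 14 of 19 (11, 15 and 16 adjusted over the list alone, adjusted p = 0.00136, 1.53e-08 and 1.10e-09, the first with adjusted p = 0.0784 with an estimated correlation), with OAS2 at 2.10, 3.70 and 4.15. ATF4 targets fell in 15, 18 and 18 of 18 (adjusted p = 1.49e-10, 4.84e-17 and 7.76e-15). G1/S genes rose in 14 of 20 at week 2 (16 adjusted over the list alone, adjusted p = 2.10e-05, adjusted p = 0.0784 with an estimated correlation), fell in 16 at week 3 (17 adjusted over the list alone, adjusted p = 1.17e-06, adjusted p = 0.0714 with an estimated correlation) and in all 20 at week 4 (adjusted p = 6.93e-12). The p53 target and CDK inhibitor list fell at week 2 in 7 of 17 genes and rose in 1 (8 and 2 adjusted over the list alone, adjusted p = 0.011, adjusted p = 0.0675 with an estimated correlation), with GDF15 at -1.39 and CDKN2C rising by 0.68. Counts higher and lower against week 1 were 3283 and 2772 at week 2, 4174 and 3799 at week 3, and 4334 and 4076 at week 4.

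Between the withdrawals, week 4 off drug against week 2 off drug, MITF rose by 1.40, TYR by 1.10 and MKI67 by 0.94, and all 20 G1/S and all 20 G2/M genes rose (adjusted p = 3.11e-14 and 5.55e-19). ATF4 targets fell in 15 of 18 and rose in 1 (adjusted p = 8.95e-12), with 2992 genes higher and 2952 lower in all. Against untreated cells, week 4 off drug had BRAF higher by 1.93, AXL by 4.35 and MITF lower at -1.93, all 17 secreted factors up (adjusted p = 6.48e-13), 18 of 20 invasive-state genes up (adjusted p = 8.33e-13) and 18 of 19 cholesterol synthesis genes down (adjusted p = 5.98e-11), with 5753 genes higher and 5257 lower. From week 2 off drug to week 3 on drug, ERK output fell in 20 of 23 and rose in 3 (adjusted p = 3.78e-12), G2/M rose in all 20 (adjusted p = 8.35e-16), COL1A1 rose by 7.22, and 5694 genes were higher and 5842 lower.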
